A study of Homo sapiens with 15 samples.

How the data were processed

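The data are microarray measurements of total RNA from 15 samples of the HMT3522 human breast epithelial series grown in a 3-dimensional laminin-rich extracellular matrix. Per the labels, S1 is the nonmalignant line (3 samples), T4 is its malignant counterpart (3 samples), and the 9 samples called T4R here are T4 cells that the submitters name reverted, each with another agent. RNA was extracted with Trizol and labelled with biotin by the standard Affymetrix protocol, per the labels' protocols, and the arrays are of the U133A kind, per the series' design text. That text mentions a vehicle control without saying which samples received it. Doses and times of the agents are not given in the sources used here.

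The deposited values come as 2 tables, one for each of 2 array types. The first table holds S1 samples 1 and 2, the 3 T4 samples and the T4R samples with GM6001, the MMP and ADAM inhibitor and LY294002. The second holds S1 sample 3 and the T4R samples with TNF protease inhibitor-2, PD98059, dominant-negative Rap1, the tyrphostin, mAb225 and AIIB2. The deposited values are on the log2 scale, as their range of 6.21 to 14.5 and their medians of 7.3 to 7.4 per sample show. The summarisation software, the background correction and the normalization the authors used, and whether both tables were normalized together, are not given in the sources used here. No cell files or detection calls were used, so a floor for undetected probe sets is unknown, and the number of arrays limits the precision.

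Both tables list the same 22215 probe sets, with no control probe sets among them. The platform annotations given with the tables assigned 1 gene to 19707 probe sets and several to 614. They left 1706 unnamed, and for 188 the annotations of the array types named different genes. Symbols were updated through the Entrez number in NCBI's RefSeq gene table for 19689 probe sets. Only probe sets with 1 gene were used, which left 12149 genes, and each gene was represented by its probe set with the highest mean log2 value over all samples. The 25% of genes with the lowest mean were left out, and 9111 were tested. Probe sets of the same gene were compared for the genes that the rule for named genes, given below, picked from every comparison and list. Among these, a second probe set passed the test in the direction opposite to the one used for HSPA4 in T4 against S1 and for UQCRB in T4R against S1. Neither gene is reported further. AREG and TP63, both on the list of genes to be reported in any case, had no such probe set and are not analysed here.

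Differential expression was tested with limma 3.58.1 in R 4.3.3 on the log2 values, using lmFit and eBayes, 2-sided, with Benjamini-Hochberg adjustment over all genes tested and a threshold of 0.05. A single fit over all 15 samples had S1, T4 and T4R as groups and the table as a fixed block, so that a constant difference between array types is fitted and removed. The T4 samples all lie in the first table. The contrast of T4 with the second table's agents therefore runs through S1 and through the agents of the first table. The table term is estimated mainly from the T4R samples, which partly fixes the difference between agents of the 2 tables. With that term in the fit, 837 genes were higher and 797 lower in the second table. Group means and SDs in the text are of the deposited values, whereas differences and their standard errors come from the fit. Nothing in the labels says that samples of a group came from separate cultures, so p-values measure only the spread between these samples, which may be technical. For T4R the spread also holds the differences between 9 agents.

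A second fit split T4R by the target named in the labels into 3 classes of 3 agents. The protease class holds GM6001, the MMP and ADAM inhibitor and TNF protease inhibitor-2. The MAPK, PI3K and Rap1 class holds PD98059, LY294002 and dominant-negative Rap1. The EGFR and ITGB1 class holds a tyrphostin, which is a kinase inhibitor, and the antibody mAb225, both against EGFR, and AIIB2 against β1-integrin. The place of dominant-negative Rap1 in its class rests on knowledge of the study and not on a label. Differences between classes were tested with limma's moderated F-test. Single agents have 1 sample each, so their values carry no test. They were set against the T4 mean after removal of the table effect, and each list median was ranked among 10000 random lists of the same size matched on mean expression. Random lists do not keep the correlation between genes of a list, so these ranks are descriptive and not tests.

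Gene lists (26) were tested with limma's camera at a preset correlation of 0.01 and again with the estimated correlation. Camera compares a list with all other genes. The self-contained rotation test fry was added after seeing the data. The rule for named genes took the 10 largest changes in each direction among genes past the threshold for T4 against S1 and for T4R against T4. It took the 5 largest in each direction for T4R against S1 and each class, the 10 smallest p for the F-test and up to 4 members with the smallest p of each list described. The genes EGFR, ITGB1, ITGA6, MMP1, MMP9, ADAM17, AREG, TGFA, RAP1A, RAP1B, CDH1, VIM, MKI67, TP63 and DUSP6 were to be given in any case. Groups, tests, lists, this rule and the alternatives, except those named as chosen later, were fixed before the data were examined. Genes named as kept in T4R, as changed in T4R alone or as apart in 1 agent sample, and genes drawn for figures, were chosen after their values were seen.

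Because T4R against T4 and T4 against S1 share the T4 samples, 100 data sets with T4R equal to T4 were simulated from the fitted means and spreads. The slopes, shares and correlations of single agents were taken from the same data sets, a choice made after seeing the data. S1 and T4 samples carry the same replicate numbers in the labels. With the table effect removed, deviations from the group mean correlated across genes at 0.191, 0.297 and 0.355 for samples of the same number, all above the bound of 0.1 set for treating the numbers as pairs. The labels themselves name no shared batch or day, and S1 sample 1 correlated as well with T4 sample 2 (0.282). Deviations from the mean of 3 samples sum to 0, so these values depend on each other, and those among samples 1 and 2 follow largely from samples 3 standing apart together. Samples 3 may share a batch, or samples 1 and 2 of a line may be repeat measurements, in which case the 3 samples of a group would count as fewer independent ones and the p-values would be too small. The fit with the replicate number as a block is therefore given as an alternative. With the table term beside it, that fit rests on pairs 1 and 2, since the samples of pair 3 lie in different tables.

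The alternatives tried were other choices of probe set, no filter and a stricter filter, quantile normalization within tables, quantile normalization across tables without the table block, a random table block, a mean-variance trend, array weights, a fold threshold, fewer groups in the fit, each table alone and leaving out each sample in turn. For all samples, the table block was dropped only together with quantile normalization across tables, called no table block below. Changes under that setting cannot be credited to either step alone. The fits were tested on simulated data drawn from the real means and spreads, with 50 of 9111 genes changed at each of 4 sizes. For T4 against S1 they called 38.0% of genes changed by 0.5 on the log2 scale, 88.0% of those changed by 1 and 100% of those changed by 2 or 3. False calls made up 8.94% of the calls. For T4R against S1 these shares were 56.0%, 90.0% and 100%, with 4.95% false calls. Plots were drawn with matplotlib 3.10.9.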

Results

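Expression was measured on Affymetrix U133A-type arrays in 15 samples of the HMT3522 breast epithelial series grown in laminin-rich matrix. S1 is a nonmalignant line that forms polarised, growth-arrested acini in such cultures, and T4 is a malignant line derived from the same series. There were 3 samples of S1, 3 of T4 and 9 of T4 treated with a reverting agent (T4R), which were an inhibitor of metalloproteinases (GM6001), of metalloproteinases and ADAM proteases, of TNF protease (TNF protease inhibitor-2), of MAPK signalling (PD98059), of PI3K (LY294002), of EGFR (a tyrphostin, which is a kinase inhibitor, and the antibody mAb225) or of β1-integrin (the antibody AIIB2), or a dominant-negative Rap1. Each agent had 1 sample. The arrays were of 2 types with a value table each, 8 samples in the first and 7 in the second, and sample medians lay between 7.3 and 7.4 on the log2 scale. S1 samples 1 and 2 differed at least 2-fold in 16 genes, and S1 sample 3, on the other array type, differed from them in 553 and 648. T4 samples 1 and 2 differed in 6 genes, and T4 sample 3, on the same array type, from them in 356 and 426. Levels are given as log2 expression with the SD over samples, and differences as log2 values with their standard error from limma. The questions the design poses are what separates T4 from S1, what the agents change in T4, and which genes then still differ from S1.

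The gene most raised in T4 over S1 was FGFBP1, which releases stored fibroblast growth factors and was 33.1-fold higher (log2 difference 5.05 ± 0.57, adjusted p = 3.93e-05), at 7.77 ± 0.99 in S1 and 12.50 ± 0.60 in T4 (SD, n = 3 each, limma). IER3, an immediate early gene, rose by 4.79 ± 0.35, and FN1, which encodes fibronectin, by 3.86 ± 0.42. The other genes with the largest rises were TNFSF10 (3.83 ± 0.65), DUSP6 (3.77 ± 0.51), CCL20 (3.67 ± 0.34), SERPINA1 (3.61 ± 0.44), AMIGO2 (3.54 ± 0.42), PHLDA1 (3.47 ± 0.21) and COL5A2 (3.39 ± 0.33). TMT1A, a methyltransferase gene, was lowest relative to S1 with a log2 difference of -4.32 ± 0.58, falling from 12.84 ± 0.06 to 8.56 ± 1.47. The next largest falls were in IGFBP3 (-4.02 ± 0.38), ITGBL1 (-3.78 ± 0.26), MRFAP1L1 (-3.73 ± 0.13), NEBL (-3.61 ± 0.43), the keratin gene KRT10 (-3.45 ± 0.45), the cornified envelope gene PPL (-3.32 ± 0.40), S100A14 (-3.23 ± 0.12), SELENBP1 (-3.20 ± 0.41) and GPM6B (-3.07 ± 0.08). IGFBP3, MRFAP1L1, S100A14 and GPM6B had T4 means of 6.73 to 6.86, below the lower quartile of each T4 sample, so their differences may be understated. All 20 passed the test with adjusted p of 0.000796 or less. In all, 2452 of 9111 genes passed, 1333 higher and 1119 lower in T4, of which 373 and 272 changed at least 2-fold. Quantile normalization within tables gave 1233 higher and 1317 lower. Within the first table alone, with 2 S1 and 3 T4 samples, 2808 genes passed, and the second table holds no T4 sample.

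Among genes of the pathways the agents address, ITGA6, the laminin receptor subunit, was 3.83-fold higher in T4 (1.94 ± 0.35, adjusted p = 0.00133). The EGFR ligand gene TGFA was higher by 1.27 ± 0.35 (adjusted p = 0.0158), the sheddase gene ADAM17 by 0.49 ± 0.11 (adjusted p = 0.00426), RAP1B by 0.85 ± 0.14 (adjusted p = 0.000764) and the proliferation marker MKI67 by 1.73 ± 0.48 (adjusted p = 0.0168). EGFR (0.84 ± 0.40, adjusted p = 0.144), ITGB1 (0.04 ± 0.11), RAP1A (0.03 ± 0.21), CDH1 (-0.59 ± 0.47, adjusted p = 0.397) and VIM (-0.14 ± 0.32) did not pass. MMP1 and MMP9 were among the dimmest genes, left out of the test, with T4 means of 6.85 ± 0.32 and 7.01 ± 0.14 against 6.61 ± 0.06 and 6.93 ± 0.02 in S1. TGFA lost its call without S1 sample 1 (adjusted p = 0.0721), S1 sample 2 (adjusted p = 0.0557) or T4 sample 3 (adjusted p = 0.0631), and MKI67 without S1 sample 2 (adjusted p = 0.0985) or T4 sample 3 (adjusted p = 0.0687). With the replicate number as a block, a fit that rests on pairs 1 and 2, EGFR (1.51, adjusted p = 0.000196) and CDH1 (-0.62, adjusted p = 0.0109) also passed. With that block but without the table, CDH1 passed (-0.62, adjusted p = 0.0451) and EGFR did not (0.68, adjusted p = 0.444). Array weights called both (adjusted p = 0.000164 for EGFR and 0.042 for CDH1), and with only S1 and T4 samples CDH1 passed (adjusted p = 0.044). Without S1 sample 3, T4 sample 3 and dominant-negative Rap1 together, a choice made after seeing the data, EGFR passed (adjusted p = 0.00377).

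Of 20 measured genes that report ERK activity, 13 were higher in T4 and 1, EPHA4, was lower (-1.99 ± 0.13), with a list median of 1.30 and the same count adjusted over the list alone. SPRY4 (2.41 ± 0.12) and FOSL1 (2.05 ± 0.12) rose beside DUSP6 and PHLDA1, the first a feedback inhibitor and the second a transcription factor of the pathway. Of 7 EGFR ligands and receptors, 3 were higher and none lower (4 when adjusted over the list alone), namely HBEGF (2.89 ± 0.17), EREG (2.52 ± 0.31) and TGFA. FOXO targets, which are held down by AKT signalling, were lower in 6 of 13 members (7 adjusted over the list alone), with PDK4 at -1.90 ± 0.11, SESN1 at -1.54 ± 0.22, CITED2 at -2.25 ± 0.41 and BCL6 at -1.56 ± 0.34. Cell division genes were higher in 12 of 25 members (18 adjusted over the list alone), among them CENPA (1.80 ± 0.36), PLK1 (1.26 ± 0.32), CDC20 (2.07 ± 0.54) and TTK (1.34 ± 0.37). Camera with the preset correlation called these 4 lists with adjusted p of 7.45e-07 for ERK output, 0.0118 for EGFR ligands and receptors, 0.00062 for FOXO targets and 2.5e-05 for cell division. With an estimated correlation none was called, at adjusted p = 0.252, 0.252, 0.276 and 0.584 in that order.

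Basement membrane genes and matrix receptors were higher in T4 in 12 of 26 members and lower in 3 (13 and 3 adjusted over the list alone). COL4A1 stood at 2.15 ± 0.25, ITGB6 at 1.82 ± 0.22, ITGA5 at 1.94 ± 0.27 and LAMB1 at -1.93 ± 0.27. NF-kappaB and cytokine genes were higher in 8 of 24 (9 adjusted over the list alone), led by PTGS2 (3.24 ± 0.15), IL1A (3.36 ± 0.30), CCL20 and the neutrophil attractant gene CXCL8 (3.33 ± 0.50). Interferon response genes were higher in 11 of 26, the same adjusted over the list alone, and those with the smallest p were HLA-B (2.57 ± 0.30), HLA-C (2.47 ± 0.31), HLA-F (1.71 ± 0.30) and ISG20 (1.42 ± 0.26). The 3 HLA genes encode class I antigen presentation molecules. Glycolysis genes were higher in 10 of 20 and lower in 2 (11 and 2 over the list alone). SLC2A3 (2.45 ± 0.24), a glucose transporter, and PFKP (2.82 ± 0.29) rose, and PFKM (-0.96 ± 0.11) and HK1 (-1.09 ± 0.15), other isoforms of glycolytic enzymes, fell. Cholesterol synthesis genes were higher in 8 of 17 (9 higher and 1 lower over the list alone), including IDI1 (2.01 ± 0.27) and INSIG1 (1.75 ± 0.31). TGF-beta response genes were higher in 7 and lower in 1 of 18 (9 and 1 over the list alone), with SKIL at 1.34 ± 0.12. Lower in T4 were 17 of 33 oxidative phosphorylation genes with 1 higher (20 and 2 over the list alone), such as CYC1 (-1.99 ± 0.14) and UQCRC2 (-1.63 ± 0.15), and 7 of 34 ribosomal protein genes, the same over the list alone, such as RPL8 (-0.76 ± 0.13). Camera's adjusted p with the preset correlation was 0.0207 for basement membrane, 3.07e-05 for NF-kappaB, 0.000223 for interferon, 0.0148 for glycolysis, 0.0102 for cholesterol, 0.0201 for TGF-beta, 1.9e-07 for oxidative phosphorylation and 0.000225 for ribosomal proteins. With an estimated correlation the adjusted p was 0.252, 0.252, 0.545, 0.252, 0.545, 0.252, 0.252 and 0.658 in that order.

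The other 14 lists were not called in T4 against S1. Of 5 measured markers of leukocytes and endothelium, with a median of -0.11 and a mean of 0.07, only CD14 passed (0.97 ± 0.26). Of the hypoxia list, 5 of 17 members were higher and 1 lower (6 and 1 over the list alone), with ANGPTL4 at 2.57 ± 0.25 and LOXL2 at 2.68 ± 0.32, at camera's adjusted p = 0.0875. Luminal markers were higher in 2 of 10 and lower in 1, with KRT18 at 0.98 ± 0.21 and GATA3 at -0.97 ± 0.34. Metalloproteinase genes and inhibitors were higher in 6 of 19 and lower in 1, with ADAMTS1 at 1.83 ± 0.20 and MMP14 at -0.47 ± 0.11. Single members that passed elsewhere included RRM2 of DNA replication (2.57 ± 0.79), PKP2 (0.97 ± 0.21) and DSG3 (-1.34 ± 0.33) of the cell junctions, TWIST1 (-1.20 ± 0.24) and S100A4 (-1.74 ± 0.36) of the mesenchymal markers, and SCD (1.95 ± 0.54) and ACSL1 (-2.11 ± 0.29) of fatty acid synthesis. HSPH1 (-1.73 ± 0.40) of the heat shock proteins, ABCC2 (-2.27 ± 0.43) of the NRF2 targets and XPC (-1.03 ± 0.33) of the p53 targets were lower, and S100A2 (0.34 ± 0.09) of the basal and SLPI (1.43 ± 0.31) of the keratinocyte markers higher. Counts of higher and lower members were 1 and 0 of 25 for DNA replication (0 and 0 over the list alone), 2 and 2 of 27 for junctions, 2 and 0 of 13 for basal markers, 2 and 2 of 16 for keratinocyte differentiation (2 and 3 over the list alone) and 1 and 2 of 15 for mesenchymal markers. They were 2 and 2 of 11 for fatty acid synthesis, 10 and 2 of 26 for ATF4 targets (adjusted p = 0.0708), 1 and 2 of 16 for p53 targets, 0 and 3 of 13 for heat shock proteins and 1 and 2 of 16 for NRF2 targets. Except where given, the list alone changed no count. The basal list had a median of 0.00 and a mean of -0.16, and the NRF2 list 0.01 and -0.12.

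The call of basement membrane genes ended with the table as a random block (adjusted p = 0.0531), in the first table alone (0.079), with only S1 and T4 samples (0.0671) and with the replicate block without the table (0.135). That of TGF-beta genes ended in the first table alone (0.0876), with only S1 and T4 samples (0.0816) and with the dimmer genes up to the median left out (0.342). MKI67 missed the threshold with the mean of all probe sets (0.98, adjusted p = 0.065). With no table block and quantile normalization across tables, MKI67 (1.37, adjusted p = 0.0893) and ADAM17 (0.32, adjusted p = 0.139) missed it. ADAM17 also missed it with the replicate block without the table (adjusted p = 0.106), and TGFA in the first table alone (adjusted p = 0.0602) and with only S1 and T4 samples (adjusted p = 0.0701). The fry test did not call cell division (adjusted p = 0.051) or ribosomal proteins (adjusted p = 0.109). Of the lists that were not called, the replicate block called DNA replication (median 0.57, adjusted p = 9.34e-06), metalloproteinases (0.46, adjusted p = 0.00787), hypoxia (0.48, adjusted p = 0.0235), ATF4 targets (0.32, adjusted p = 0.0393) and, with its median turned to -0.30, NRF2 targets (adjusted p = 0.00372). With the replicate block without the table, DNA replication (0.34, adjusted p = 0.00647) and metalloproteinases (0.39, adjusted p = 0.0484) were called, but not hypoxia (adjusted p = 0.183), ATF4 (adjusted p = 0.053) or NRF2 targets (adjusted p = 0.529). Metalloproteinases were called under 8 further settings. These were the probe set with the largest interquartile range (adjusted p = 0.0255), the mean of all probe sets (0.0201), no filter (0.0328), quantile normalization within tables (0.0429), only S1 and T4 samples (0.0244), the first table alone (0.031), the fit without the 3 samples named above (0.021) and fry (0.00088). DNA replication was called with no filter (adjusted p = 0.0385), only S1 and T4 samples (7.27e-05), the first table alone (2.34e-05) and without the 3 samples (8.92e-05). Hypoxia was called with no filter (adjusted p = 0.0385), no table block (0.0396) and without the 3 samples (0.00612), ATF4 targets with no filter (0.0251), without the 3 samples (0.0181) and by fry (0.00082), and NRF2 targets without the 3 samples (-0.30, adjusted p = 0.0152). Leaving out T4 sample 3 called hypoxia (0.45, adjusted p = 0.000526), metalloproteinases and ATF4 targets (adjusted p = 0.0187 each) and NRF2 targets (-0.19, adjusted p = 0.046), and lowered the NF-kappaB median from 0.51 to 0.34. DNA replication was called without S1 sample 3 (0.94, adjusted p = 9.92e-05), T4 sample 1 (0.0412), T4 sample 2 (0.0315) or dominant-negative Rap1 (0.045). Hypoxia was called without S1 sample 2 (0.0362), ATF4 without S1 sample 1 (0.0494) and metalloproteinases without dominant-negative Rap1 (0.0499). The TGF-beta median went from 0.57 to 0.37 without T4 sample 1, and the ribosomal one from -0.23 to -0.14 without S1 sample 1.

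**Figure D1:**
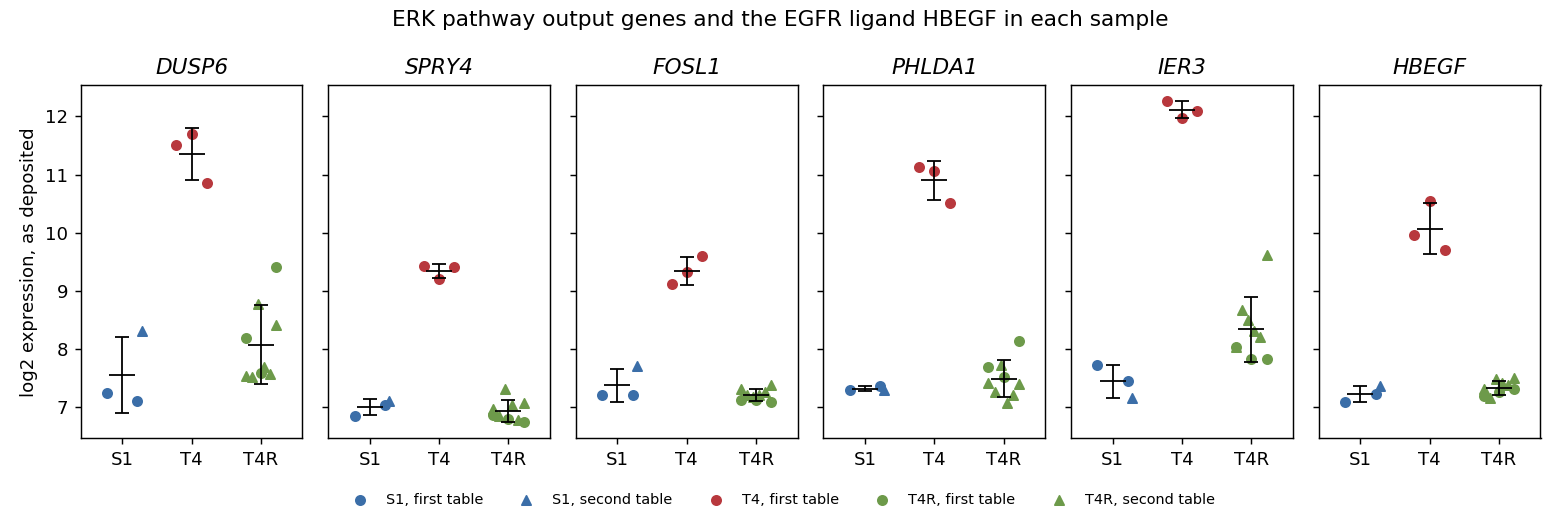
Deposited log2 expression (y axis) of 6 genes in each sample of S1, T4 and T4R (x axis), with circles for the first table and triangles for the second; horizontal marks are group means and error bars SDs. DUSP6 lies at 7.56 ± 0.66 in S1, 11.35 ± 0.45 in T4 and 8.08 ± 0.67 in T4R, and the T4R samples lie below every T4 sample in all 6 genes.

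The reverting agents, taken as 9 samples of a single group, lowered most of the genes that stood highest in T4. FGFBP1 fell by 4.53 ± 0.53 to a mean of 8.61 ± 0.86 (SD, n = 9, limma adjusted p = 0.000116), IER3 by 4.03 ± 0.32 and FN1 by 3.93 ± 0.39. Large falls were also seen for the matrix gene THBS1 (-3.38 ± 0.41), ZBED2 (-3.31 ± 0.36), DUSP6 (-3.22 ± 0.47), PHLDA1 (-3.18 ± 0.19), the prostaglandin synthase gene PTGS2 (-3.14 ± 0.14), BHLHE40 (-3.03 ± 0.28) and AMIGO2 (-3.02 ± 0.39). TMT1A rose by 3.44 ± 0.54 to 11.90 ± 0.53, and PPL by 3.32 ± 0.37 to 11.23 ± 0.30, against 11.24 ± 0.34 in S1. The next largest rises were in MATN2 (2.44 ± 0.33), RETREG1 (2.20 ± 0.32), CITED2 (2.19 ± 0.38), SELENOP (2.19 ± 0.43), the small heat shock protein gene CRYAB (2.18 ± 0.53), GSTA4 (2.11 ± 0.39), TGFBR3 (2.09 ± 0.40) and ASS1 (2.08 ± 0.48). All 20 passed the test, with adjusted p up to 0.0149 for CRYAB, which missed it without T4 sample 3 (adjusted p = 0.051). In all, 1358 genes passed, 589 higher and 769 lower, of which 98 and 206 changed at least 2-fold. Quantile normalization within tables gave 728 higher and 674 lower. The first table alone, which holds 3 T4 and 3 T4R samples, gave 1395 genes, and there ASS1 missed the threshold (1.77, adjusted p = 0.0632).

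ITGA6 fell by 1.90 ± 0.33 (adjusted p = 0.00203) to 10.43 ± 0.44, against 10.30 ± 0.67 in S1. TGFA fell by 1.42 ± 0.32 (adjusted p = 0.0103), ADAM17 by 0.40 ± 0.10 (adjusted p = 0.0167) and MKI67 by 1.60 ± 0.45 (adjusted p = 0.0284). RAP1B (-0.36 ± 0.13, adjusted p = 0.0893), VIM (-0.76 ± 0.30, adjusted p = 0.109), CDH1 (0.74 ± 0.44, adjusted p = 0.297), RAP1A (0.21 ± 0.20), EGFR (0.02 ± 0.37) and ITGB1 (0.01 ± 0.10) did not pass. MKI67 lost its call when S1 sample 3, T4 sample 1, T4 sample 3, GM6001, the MMP and ADAM inhibitor or LY294002 was left out, with adjusted p of 0.051, 0.057, 0.122, 0.0521, 0.0537 and 0.0607. ADAM17 lost its call without T4 sample 2 (adjusted p = 0.0663) or LY294002 (adjusted p = 0.0512), and with a random table block (-0.32, adjusted p = 0.0663). With no table block and quantile normalization across tables, ADAM17 (-0.12, adjusted p = 0.538) and MKI67 (-0.96, adjusted p = 0.164) did not pass. Within the first table TGFA missed the threshold (-1.33, adjusted p = 0.0775), and RAP1B (-0.44, adjusted p = 0.031) and VIM (-0.80, adjusted p = 0.0426) passed. RAP1B also passed with no table block (adjusted p = 0.0157), a random one (0.0432), array weights (0.00254), only T4 and T4R samples (0.0364) and without S1 sample 3, T4 sample 3 and dominant-negative Rap1 together (0.0246). VIM passed with no table block (adjusted p = 0.0169), array weights (0.000399) and without those 3 samples (0.0242), and CDH1 with array weights (0.87, adjusted p = 0.00798).

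ERK output genes were lower in T4R in 10 of 20 members and higher in 1 (15 and 1 adjusted over the list alone), with a median of -1.08. SPRY4 (-2.54 ± 0.11) and FOSL1 (-2.29 ± 0.11) fell, FOSL1 to 7.21 ± 0.10, against 7.38 ± 0.29 in S1. The EGFR ligand genes HBEGF (-2.83 ± 0.15) and EREG (-2.29 ± 0.29) fell with TGFA, 3 of the 7 in their list, the same over the list alone. FOXO targets rose in 4 of 13, the same over the list alone, namely SESN1 (1.29 ± 0.20), CDKN1B (1.15 ± 0.19), CITED2 and BCL6 (1.24 ± 0.32). Basement membrane genes and receptors were lower in 10 of 26 and higher in 1 (12 and 1 over the list alone), with COL4A1 at -2.62 ± 0.23, ITGA5 at -2.22 ± 0.25, COL4A2 at -1.86 ± 0.21 and ITGA2 at -1.80 ± 0.21. Metalloproteinase genes and inhibitors were lower in 5 of 19 and higher in 1 (9 and 1 over the list alone), among them ADAMTS1 (-1.58 ± 0.18), the plasminogen system genes PLAT (-1.56 ± 0.25) and PLAUR (-1.10 ± 0.19), and TIMP1 (-1.32 ± 0.29), which is an inhibitor and not a protease. Camera's adjusted p with the preset correlation was 2.48e-11 for ERK output, 0.00232 for EGFR ligands and receptors, 0.000754 for FOXO targets, 0.000754 for basement membrane and 0.0128 for metalloproteinases. With an estimated correlation the adjusted p was 0.0552, 0.121, 0.336, 0.106 and 0.163 in that order, none past the threshold.

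Hypoxia response genes were lower in T4R in 7 of 17, the same over the list alone, with ANGPTL4 (-2.61 ± 0.23), BHLHE40, LOXL2 (-2.70 ± 0.30) and VEGFA (-2.03 ± 0.30). T4 sample 3 stood apart in this list, with a mean of 8.97 inside the T4R range of 8.60 to 9.18, against 10.11 and 9.87 in T4 samples 1 and 2. The list median of -0.26 became -0.86 without T4 sample 3, -0.03 without T4 sample 1, -0.13 without T4 sample 2 and -0.14 without LY294002, at adjusted p of 0.0109 or less. Glycolysis genes were lower in 8 of 20 and higher in 1 (10 and 1 over the list alone), with PFKP at -2.65 ± 0.27, SLC2A3 at -1.50 ± 0.22, LDHA at -0.62 ± 0.12 and PFKM at 0.82 ± 0.10. NF-kappaB and cytokine genes were lower in 5 of 24 and higher in 1 (6 and 1 over the list alone), with CCL20 at -2.94 ± 0.31, CXCL8 at -2.65 ± 0.46 and IL1A at -1.32 ± 0.27. Cholesterol synthesis genes were lower in 8 of 17 (9 lower and 1 higher over the list alone), including IDI1 (-1.06 ± 0.25), HMGCS1 (-1.11 ± 0.26) and SQLE (-0.71 ± 0.18). Genes of ATF4 and the unfolded protein response were lower in 7 of 26 and higher in 2 (8 and 2 over the list alone), with TRIB3 at -1.43 ± 0.19 and the amino acid transporter gene SLC3A2 at 1.19 ± 0.16. TGF-beta response genes were lower in 6 of 18 and higher in 2, the same over the list alone, with SKIL at -1.11 ± 0.11 and PMEPA1 at -1.39 ± 0.17. Oxidative phosphorylation genes were higher in 5 of 33 (11 over the list alone), among them SDHD (0.81 ± 0.10) and NDUFA2 (0.65 ± 0.09). Cell division genes had a median of -0.74, but only MKI67 of 25 passed and none over the list alone. No ribosomal protein gene of 34 passed, at a median of 0.22. Camera's adjusted p with the preset correlation was 0.000754 for hypoxia, 0.000659 for glycolysis, 0.0054 for NF-kappaB, 0.00408 for cholesterol, 0.0054 for ATF4, 0.0128 for TGF-beta, 5.2e-06 for oxidative phosphorylation, 0.000806 for cell division and 0.000122 for ribosomal proteins. With an estimated correlation the adjusted p was 0.46, 0.106, 0.46, 0.46, 0.106, 0.247, 0.336, 0.701 and 0.644 in that order.

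The other 12 lists were not called in T4R against T4. Of 16 p53 targets, 5 were lower and 1 higher (6 and 2 over the list alone, adjusted p = 0.07), with the death receptor gene TNFRSF10B at -1.22 ± 0.23, FAS at -0.87 ± 0.21 and SESN1 higher. Of 25 DNA replication genes none passed (adjusted p = 0.0642). Higher and lower members were 3 and 1 of 27 for cell junctions, with DSG3 (1.28 ± 0.31), EPCAM (0.93 ± 0.24), PKP1 (1.10 ± 0.30) and the P-cadherin gene CDH3 (-0.54 ± 0.14). They were 0 and 2 of 10 for luminal markers, with KRT18 (-1.07 ± 0.19) and XBP1 (-0.60 ± 0.17), and 0 and 2 of 13 for basal markers (1 and 2 over the list alone), with S100A2 (-0.47 ± 0.08) and ACTA2 (-0.55 ± 0.11). Fatty acid synthesis had 2 and 1 of 11, with ELOVL5 (0.95 ± 0.17), ACSL1 (1.49 ± 0.27) and SCD (-2.17 ± 0.50). The counts were 2 and 1 of 26 for interferon, 1 and 0 of 13 for heat shock proteins (CRYAB), 2 and 0 of 16 for NRF2 targets, 0 and 1 of 16 for keratinocyte differentiation (CRABP2, -0.69 ± 0.10), 0 and 1 of 15 for mesenchymal markers (FN1) and 0 and 0 of 5 for leukocyte and endothelial markers. The mesenchymal list had a median of 0.02 and a mean of -0.35.

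The metalloproteinase call ended with the table as a random block (adjusted p = 0.0941) or with no table block and quantile normalization across tables (0.0819). The ribosomal call ended with a random block (0.0941), and the NF-kappaB (0.0816) and TGF-beta calls (0.517) with the dimmer genes up to the median left out. Without S1 sample 3, T4 sample 3 and dominant-negative Rap1 together, a choice made after seeing the data, FOXO targets (median 0.19, adjusted p = 0.061) and ribosomal proteins (0.02, adjusted p = 0.411) were not called, and DNA replication turned to 0.14 (adjusted p = 0.0288). The NF-kappaB call ended without LY294002 (-0.17, adjusted p = 0.0509). Without T4 sample 3 alone, list medians went from -0.29 to -0.08 for NF-kappaB, 0.69 to 0.29 for FOXO targets, -0.64 to -0.43 for EGFR ligands and receptors, -0.74 to -0.44 for cell division, -0.37 to -0.56 for TGF-beta and 0.22 to 0.10 for ribosomal proteins, still called. Without S1 sample 3 the ribosomal median was also 0.10. Without S1 sample 3, T4 sample 3 and dominant-negative Rap1 together, heat shock proteins (0.22, adjusted p = 0.0287), NRF2 targets (0.33, adjusted p = 0.0135), mesenchymal markers (-0.15, adjusted p = 0.0426) and p53 targets (adjusted p = 0.0414) were called. DNA replication was called with the largest-range probe set (-0.34, adjusted p = 0.0403), the mean of all probe sets (0.0468), no filter (0.0343) and quantile normalization within tables (0.0415). The p53 targets were called with no filter (adjusted p = 0.0343), quantile normalization within tables (0.0448) and by fry (0.0305), whereas fry did not call cell division (0.281) or ribosomal proteins (0.189). With a single sample left out, calls were gained by p53 targets without T4 sample 3 (adjusted p = 0.013), the MMP and ADAM inhibitor (0.0317) or AIIB2 (0.0302), and by NRF2 targets without T4 sample 3 (0.00738). Interferon genes gained one without LY294002 (0.30, adjusted p = 0.0026), and DNA replication without T4 sample 1 (0.0158), T4 sample 2 (0.0139), GM6001 (0.015), the MMP and ADAM inhibitor (0.00859) or LY294002 (0.0323). MKI67 missed the threshold with the mean of all probe sets (adjusted p = 0.106) or only T4 and T4R samples (adjusted p = 0.0567).

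After the agents, the largest excess of T4R over S1 was in MSLN, which encodes the surface protein mesothelin (3.53 ± 0.33, adjusted p = 1.06e-05), followed by COL5A2 (3.22 ± 0.27), TNFSF10 (3.18 ± 0.54), the complement gene C3 (3.04 ± 0.22) and LGALS3BP (2.78 ± 0.17). MSLN stood at 7.56 ± 0.80 in S1, 9.64 ± 0.40 in T4 and 11.15 ± 0.44 in T4R, so that it was higher in T4R than in T4 as well (1.39, adjusted p = 0.0237), as was C3 (1.77, adjusted p = 0.000531). Lowest relative to S1 were MRFAP1L1 (-3.69 ± 0.11), IGFBP3 (-3.66 ± 0.31), S100A14 (-3.18 ± 0.10), KRT10 (-3.10 ± 0.37) and GPM6B (-3.10 ± 0.07), the last at 9.82 ± 0.10 in S1 and 6.74 in both T4 and T4R. Apart from KRT10, these genes had T4 and T4R means of 6.73 to 6.86, below the lower quartile of each of those samples (6.87 or more). With no known floor, their differences may be understated. Interferon response genes were higher than in S1 in 14 of 26 members and lower in none (19 over the list alone), with HLA-B at 2.76 ± 0.25, HLA-C at 2.64 ± 0.26, BST2 at 0.92 ± 0.12 and the immunoproteasome gene PSMB9 at 1.88 ± 0.25. Of 16 p53 targets, 7 were lower and none higher, the same over the list alone, among them TNFRSF10B (-1.19 ± 0.21), FAS (-0.88 ± 0.19), BAX (-0.65 ± 0.14) and DDB2 (-0.80 ± 0.19). NF-kappaB genes were higher in 4 of 24, with IL1A at 2.03 ± 0.24 and TNFAIP3 at 2.01 ± 0.38, and oxidative phosphorylation genes lower in 7 of 33 and higher in 1, with CYC1 at -1.73 ± 0.11, both the same over the list alone. Of 25 cell division genes 1, CENPA, was higher (0.94 ± 0.30), and none over the list alone. Camera's adjusted p with the preset correlation was 2.84e-08 for interferon, 0.00449 for p53 targets, 0.0118 for NF-kappaB, and 0.0422 for oxidative phosphorylation and for cell division. With an estimated correlation the adjusted p was 0.992 for each of the 5. The 21 other lists were not called, at adjusted p of 0.778 or more. The ERK output genes had 3 higher and 2 lower of 20 and a median of 0.12.

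In all, 2116 genes differed between T4R and S1, 1078 higher and 1038 lower in T4R, and 1106 and 1052 after quantile normalization within tables. The first table alone gave 1821 genes and the second 1165, where the single S1 sample is assumed to vary like the other groups. RAP1B was higher in T4R than in S1 (0.49 ± 0.12, adjusted p = 0.00845) and VIM lower (-0.90 ± 0.27, adjusted p = 0.0259). EGFR did not pass (0.86 ± 0.33, adjusted p = 0.0808), nor did ITGA6 (0.04 ± 0.29), TGFA (-0.15 ± 0.29), MKI67 (0.13 ± 0.40), DUSP6 (0.54 ± 0.42), ADAM17 (0.09 ± 0.09), CDH1 (0.15 ± 0.39), RAP1A (0.24 ± 0.18) or ITGB1 (0.04 ± 0.09). VIM lost its call without S1 sample 1, 2 or 3 (adjusted p = 0.0852, 0.0637 and 0.0791), GM6001 (adjusted p = 0.0523) or the MMP and ADAM inhibitor (adjusted p = 0.062), and in the second table alone (-0.79, adjusted p = 0.352). RAP1B lost its call without S1 sample 3 (0.29, adjusted p = 0.157) and in the first table alone (0.29, adjusted p = 0.127). EGFR passed with only S1 and T4R samples (adjusted p = 0.0437) and with array weights (0.00116), as DUSP6 did with array weights (0.0382). The fry test did not call NF-kappaB genes (adjusted p = 0.142), cell division (0.746) or oxidative phosphorylation (0.252). The NF-kappaB call ended in the first table alone (adjusted p = 0.109), without S1 sample 3 (0.13, adjusted p = 0.136), and without S1 sample 3, T4 sample 3 and dominant-negative Rap1 together (0.0757). That of p53 targets ended with the dimmer genes up to the median left out (adjusted p = 0.0712), without S1 sample 3 (0.0879) and without those 3 samples (0.0661). Without them EGFR (1.23, adjusted p = 0.00793), DUSP6 (1.21, adjusted p = 0.0458), DNA replication (0.74, adjusted p = 6.18e-09), hypoxia (-0.46, adjusted p = 0.0171) and ribosomal proteins (-0.24, adjusted p = 1.73e-05) passed or were called, which they were not with all samples. The cell division call ended with quantile normalization within tables (adjusted p = 0.0632), with the dimmer genes left out (0.0875) and in the second table alone (0.758). It also ended without S1 sample 2 (0.731), GM6001 (0.0882), the MMP and ADAM inhibitor (0.0884), TNF protease inhibitor-2 (0.059), PD98059 (0.0579), LY294002 (0.0554), the tyrphostin (0.0518) or AIIB2 (0.0524), and the median was 0.74 without S1 sample 3. The oxidative phosphorylation call ended with quantile normalization within tables (0.149), in the second table alone (0.655), with the mean of all probe sets (0.069) and with only S1 and T4R samples (0.0568). It also ended without S1 sample 2 (0.393), T4 sample 3 (0.0535), GM6001 (0.0882), PD98059 (0.0579), LY294002 (0.14), dominant-negative Rap1 (-0.09, adjusted p = 0.0635) or mAb225 (0.0521). Without S1 sample 3 alone, DNA replication (0.74, adjusted p = 4.38e-05) and ribosomal proteins (-0.24, adjusted p = 4.27e-05) were called. In the first table alone, DNA replication (0.74, adjusted p = 1.06e-05) and ribosomal proteins (-0.24, adjusted p = 0.00015) were called. The DNA replication mean of S1 sample 3 was 9.45 as deposited and 9.20 with the table effect removed, against 7.95 and 7.96 in S1 samples 1 and 2. The second table sets the agents against that sample alone. The medians there, -0.80 for DNA replication and 0.24 for ribosomal proteins, largely restate the level of that sample and were not taken as tests, and the calls that ended there rest on it too.

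Of the 2452 genes that differed between T4 and S1, 826 (33.7%) moved back in T4R past the threshold, 522 of those higher in T4 and 304 of those lower. Among these, 677 no longer passed against S1, 125 still differed from S1 in the direction of T4 and 24 had gone past S1. A further 602 genes (24.6%) passed neither against T4 nor against S1, and 21 moved further from S1. Another 1003 genes (40.9%) did not pass against T4 and still differed from S1. The genes of this kind with the largest difference in T4 were TNFSF10, COL5A2, SCRN1, HLA-B and HLA-C on the higher side and IGFBP3, MRFAP1L1, NEBL, KRT10 and S100A14 on the lower. By list, 10 of 14 ERK output genes and 10 of 15 basement membrane genes changed in T4 moved back. Of 11 interferon response genes 1 moved back and 10 did not pass against T4 and still differed from S1. Of 12 cell division genes 1 moved back and 1 was kept in that way, and the others passed neither against T4 nor against S1. Differences between lists were not tested. A further 511 genes changed in T4R without having passed in T4 against S1, 273 higher and 238 lower, and MATN2 (2.44), SELENOP (2.19) and TRIM29 (1.83) rose and SERPINE2 (-2.49), PRSS3 (-2.05) and EMP3 (-2.04) fell most among them.

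Both contrasts use the same T4 samples, which alone sets them against each other. Across genes, which are not independent replicates, the 2 log2 differences had a correlation of -0.672, against -0.199 in simulations with T4R equal to T4. Their covariance was -0.176 against -0.0219 simulated, a difference of -0.154. Of the T4-changed genes, 86.1% had the opposite sign in T4R against T4, compared with 61.7% simulated. The simulated share moving back past the threshold was 0.000318%, which follows from the setting. With T4R equal to T4, 0.03 genes on average passed in T4R against T4, so that share says nothing about the direction of change. Independent lists of these sizes would share 113 genes higher in T4 and lower in T4R and 72.3 genes lower in T4 and higher in T4R, where 522 and 304 were observed. The contrasts share the T4 samples and are not independent, so part of that excess is built in. The simulated sets did not match the data in the count of T4-changed genes. They called 3130 on average (3042 to 3222), where 2452 were observed. Their spreads came from the fit over all groups, whereas T4 sample 3 lay at least 2-fold from T4 samples 1 and 2 in 356 and 426 genes. The shared part may therefore be larger than simulated. The 3 T4 samples were not divided between the contrasts, since 1 part would have held a single sample, so part of the excess may come from them.

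**Figure D2:**
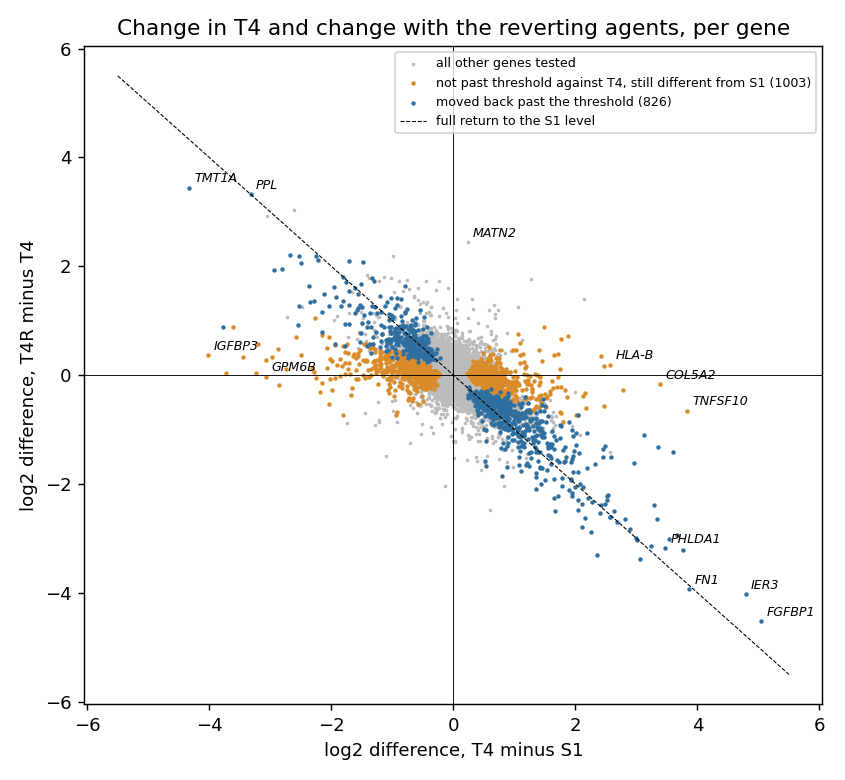
Log2 difference of T4 from S1 (x axis) against that of T4R from T4 (y axis) for 9111 genes, as points; blue points are the 826 genes that moved back past the threshold, orange points the 1003 that did not pass against T4 and still differed from S1, and the dashed line marks a full return to the S1 level. FGFBP1, IER3 and FN1 lie near that line, whereas COL5A2, HLA-B, IGFBP3 and GPM6B lie near 0 on the y axis.

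In each of the 3 target classes FGFBP1 fell and TMT1A rose relative to T4. The FGFBP1 difference was -4.26 ± 0.58 with the protease agents, -4.86 ± 0.65 with the MAPK, PI3K and Rap1 agents and -5.03 ± 0.74 with the EGFR and ITGB1 agents, and TMT1A rose by 3.63 ± 0.60, 3.07 ± 0.67 and 3.63 ± 0.77. The protease agents also raised PPL (3.19 ± 0.42), MATN2 (2.48 ± 0.37), GSTA4 (2.18 ± 0.44) and RETREG1 (2.13 ± 0.38) and lowered IER3 (-4.19 ± 0.34), FN1 (-4.10 ± 0.39), DUSP6 (-3.53 ± 0.48) and THBS1 (-3.40 ± 0.42). With the MAPK, PI3K and Rap1 agents, PPL (3.55 ± 0.47), CITED2 (2.60 ± 0.44), SELENOP (2.51 ± 0.43) and the interleukin receptor gene IL1R1 (2.51 ± 0.54) rose, and IER3 (-3.87 ± 0.38), ZBED2 (-3.63 ± 0.43), FN1 (-3.55 ± 0.44) and PLEK2 (-3.20 ± 0.24) fell. With the EGFR and ITGB1 agents, KRT16, a keratin of stratified epithelia, had a fitted rise of 4.88 ± 1.30 (adjusted p = 0.0487). That size depended on the processing and the samples. It was 3.82 with no table block and quantile normalization across tables, and 3.11 without S1 sample 3. AIIB2 read highest at 12.94 as deposited, with 11.98 as the next agent and a T4 mean of 8.37 ± 0.48. The KRT16 call was lost with the largest-range probe set (adjusted p = 0.0506), the mean of all probe sets (0.0507) or no filter (0.0678). It was also lost without S1 sample 1 (0.0839) or 2 (0.0747), T4 sample 1 (0.1), 2 (0.0617) or 3 (0.0836), GM6001 (0.0571), the MMP and ADAM inhibitor (0.0797), dominant-negative Rap1 (0.064), the tyrphostin (0.0961), mAb225 (0.0893) or AIIB2 (0.0918). CRYAB (3.35 ± 0.62), PPL (3.35 ± 0.54) and HPGD (2.75 ± 0.52) rose too. HPGD was not past the threshold with no table block and quantile normalization across tables (1.17, adjusted p = 0.238) or with a random block (2.01, adjusted p = 0.0679). TMT1A missed the threshold in this class without TNF protease inhibitor-2 (adjusted p = 0.0533), the tyrphostin (0.0638) or mAb225 (0.0614), and in the MAPK, PI3K and Rap1 class without LY294002 (0.0764). FN1 (-4.29 ± 0.50), THBS1 (-4.02 ± 0.53), AMIGO2 (-3.65 ± 0.49) and ZBED2 (-3.61 ± 0.49) fell in that class. Counts against T4 were 986 genes for the protease agents (419 higher, 567 lower), 824 for the MAPK, PI3K and Rap1 agents (335 and 489) and 561 for the EGFR and ITGB1 agents (231 and 330). After quantile normalization within tables the higher and lower counts were 518 and 510, 491 and 419, and 306 and 272 in that order, which turned the balance in each class. The protease count was 580 without T4 sample 1, 449 without GM6001, 368 without the MMP and ADAM inhibitor and 657 without TNF protease inhibitor-2, and the MAPK, PI3K and Rap1 count 392 without LY294002. The EGFR and ITGB1 class lies wholly in the second table and T4 wholly in the first, and its count was 333 without S1 sample 1, 346 without S1 sample 2, 288 without T4 sample 1, 352 without GM6001, 287 without the MMP and ADAM inhibitor, 363 without TNF protease inhibitor-2, 194 without the tyrphostin and 210 without mAb225. With no table block and quantile normalization across tables it was 1243.

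Of 20 ERK output genes, 10 passed as lower for the protease agents, 9 for the MAPK, PI3K and Rap1 agents and 9 for the EGFR and ITGB1 agents, none as higher, and medians of -1.36, -0.74 and -1.07. Adjusted over the list alone, 16, 10 and 11 were lower and 1 higher in each. The call held with an estimated correlation for the protease agents (adjusted p = 0.0362) and not for the other classes (adjusted p = 0.0843 and 0.0748). Cholesterol synthesis genes were lower in 4, 11 and 9 of 17 members (8, 12 and 10 over the list alone), with adjusted p of 0.369, 0.0843 and 0.139 with an estimated correlation. VIM passed in the EGFR and ITGB1 class (-1.33 ± 0.32, limma adjusted p = 0.033), and ITGA6 in all 3 classes, at -1.97 ± 0.37, -1.72 ± 0.41 and -2.13 ± 0.47. DUSP6 also passed in all 3, at -3.53 ± 0.48, -2.67 ± 0.54 and -3.29 ± 0.62. TGFA (-1.62 ± 0.34, adjusted p = 0.0114) and ADAM17 (-0.40 ± 0.12, adjusted p = 0.0463) passed with the protease agents only. MKI67 passed with the MAPK, PI3K and Rap1 agents only (-2.08 ± 0.52, adjusted p = 0.0316). EGFR, ITGB1, RAP1A, RAP1B and CDH1 passed in none.

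Tested against each other, the classes did not differ in any single gene. The moderated F-test of limma called 0 of 9111 genes, with 496 at an unadjusted p under 0.05, and array weights, another weighting in the same tool, called 18. The smallest p were those of the cholesterol synthesis genes IDI1 and MSMO1 (adjusted p = 0.323 for both), followed by MEGF6, MOCOS, INPP1, CARS2, F12, SKP2, TMEM164 and PON2. IDI1 lay 0.69 and MSMO1 0.83 higher with the protease agents than with the EGFR and ITGB1 agents. The count was 10 without PD98059 and 1 without TNF protease inhibitor-2. Of the 26 list means, cholesterol synthesis alone differed between the classes (adjusted p = 0.0144), 0.43 higher with the protease agents and -0.13 with the MAPK, PI3K and Rap1 agents relative to the EGFR and ITGB1 agents. This call was lost without GM6001 (adjusted p = 0.062), the MMP and ADAM inhibitor (adjusted p = 0.075), TNF protease inhibitor-2 (adjusted p = 0.0643) or LY294002 (adjusted p = 0.0745).

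In each of the 9 agent samples the T4-changed genes lay toward S1 from the T4 mean. The slope of an agent's difference from T4 on the difference of T4 from S1 lay between -0.466 for GM6001 and -0.565 for mAb225. With T4R simulated equal to T4, the shared T4 samples alone gave slopes of -0.0556 to -0.0542 on average over 100 data sets, and none beyond -0.0838. Genes higher in T4 lay below the T4 mean in 80.2% to 86.9% of cases, and genes lower in T4 lay above it in 75.2% to 81.4%. The simulated averages were 57.5% to 58.0% and 57.9% to 58.5%, and the highest simulated shares 61.4% and 61.6%. The ERK output median was below T4 with every agent, from -0.77 with dominant-negative Rap1 to -1.47 with TNF protease inhibitor-2, and lay at percentile 0 of the 10000 random lists each time. That rank is not a test, since random lists ignore the correlation between genes of the list and all agents share the T4 mean. Because all slopes rest on the same T4 and S1 samples, the 9 values are not independent, and the simulation has the limits given above. No T4 sample lies in the second table. The values of its agents rest on the removed table effect, which is estimated mainly from the T4R samples. That partly sets them to the level of the first-table agents. Within the first table the ERK output medians were -0.92 with GM6001, -1.38 with the MMP and ADAM inhibitor and -0.95 with LY294002.

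Across genes, the differences of GM6001 and of the MMP and ADAM inhibitor from T4 correlated at 0.955, with 3 genes at least 2-fold apart. TNF protease inhibitor-2, measured on the other array type, correlated with them at 0.895 and 0.907, with 16 and 8 genes 2-fold apart, and 89 each as deposited, before removal of the table effect. With the table effect removed, some agents against other targets correlated about as closely as TNF protease inhibitor-2 did. GM6001 correlated at 0.902 with the tyrphostin and at 0.892 with mAb225 and with PD98059, and the MMP and ADAM inhibitor at 0.907 with the tyrphostin. As deposited these agents lay further from GM6001 than TNF protease inhibitor-2 did, with 157, 182 and 190 genes 2-fold apart in that order. The MMP and ADAM inhibitor then lay 163 genes from the tyrphostin. Other agents correlated less closely with GM6001, at 0.797 for AIIB2 and 0.713 for dominant-negative Rap1. LY294002 lies in the first table and needs no table correction. It correlated at 0.828 with GM6001 and 0.817 with the MMP and ADAM inhibitor, with 72 and 99 genes 2-fold apart. The removed table effect is estimated mainly from the T4R samples, which partly fixes the difference between agents of the 2 tables. The EGFR antibody mAb225 and the EGFR tyrphostin correlated at 0.963 with 0 genes 2-fold apart, and PD98059 with the tyrphostin at 0.949 and with mAb225 at 0.952. The shared T4 mean raises all these correlations. With T4R simulated equal to T4, they averaged 0.248 to 0.25 within the first table, 0.311 to 0.315 within the second and 0.416 to 0.42 between tables. Genes are not independent replicates, and with 1 sample per agent the differences carry no test.

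Dominant-negative Rap1 differed at least 2-fold from each of the other 8 agents in 256 to 438 genes (correlations of 0.613 to 0.713), where the other pairs of agents differed in 0 to 173. It lay at least 2-fold from T4 in 663 genes, against 328 to 512 for the other 8. RAP1A, one of the Rap1 genes, read 10.91 in that sample and 10.06 to 10.71 in the other T4R samples as deposited, and the labels do not say from which Rap1 gene the dominant-negative form derives. Its cell division median lay 2.10 below T4, against -0.22 to -0.79 with the other agents. AIIB2 was the only agent with a keratinocyte differentiation median above T4 (0.65, percentile 100), where the others lay between -0.48 and -0.05. KRT16 read 12.94 in that sample and 9.80 to 11.98 with the other agents, as deposited. Cholesterol synthesis genes lay lowest with dominant-negative Rap1 (-1.02) and LY294002 (-0.84) and highest with the MMP and ADAM inhibitor (-0.23).

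**Figure D3:**
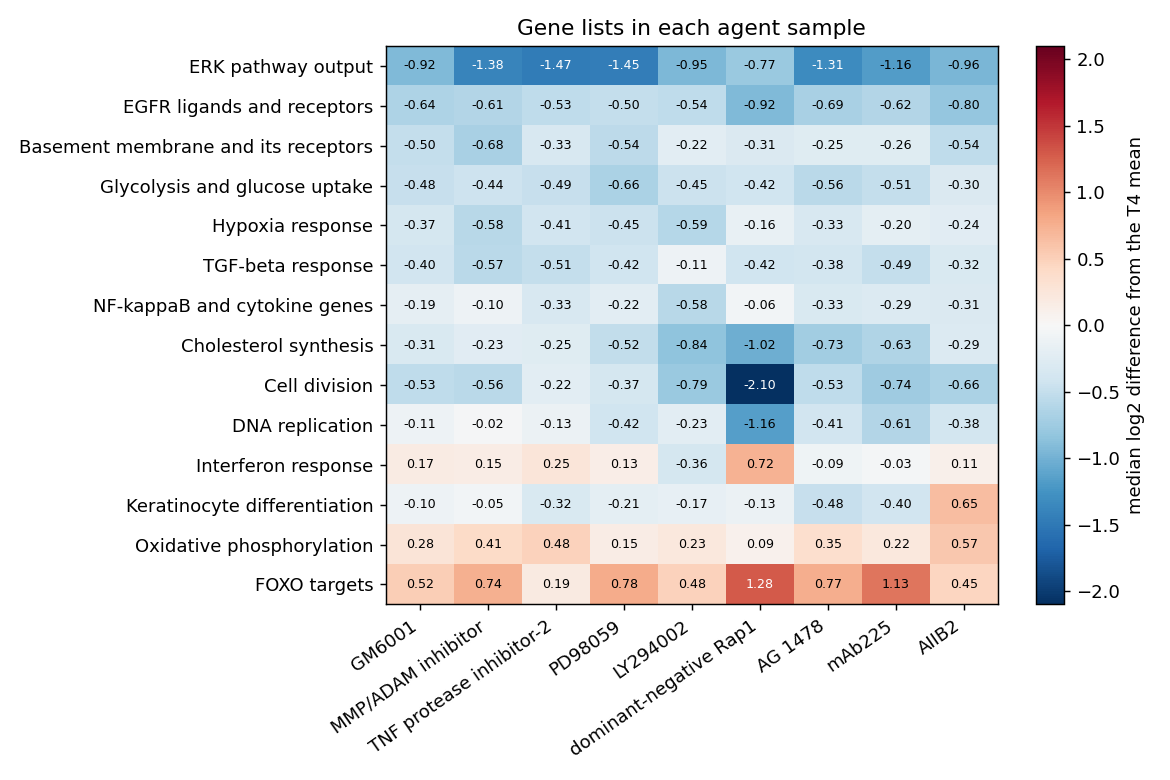
Median log2 difference from the T4 mean (colour and printed number) of 14 gene lists (rows) in each of the 9 agent samples (columns, with the tyrphostin under its AG code), with the array type effect removed. ERK output is below 0 in all 9 columns, cell division is lowest with dominant-negative Rap1 (-2.10), and keratinocyte differentiation is above 0 with AIIB2 only (0.65).

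**Figure D4:**
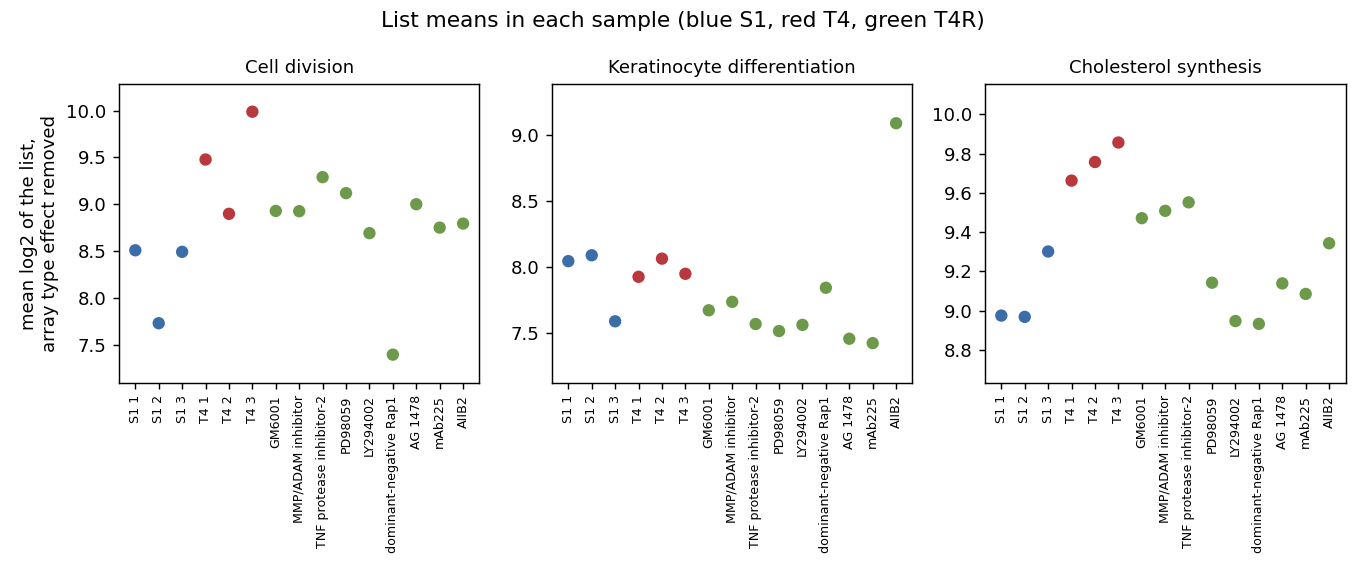
Mean log2 expression (y axis, array type effect removed) of 3 gene lists in each of the 15 samples (x axis), as points coloured by group, 1 point per sample without error bars. The dominant-negative Rap1 sample has the lowest cell division mean (7.39), the AIIB2 sample the highest keratinocyte differentiation mean (9.09), and the 3 T4 samples the highest cholesterol synthesis means.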

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

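The tests of array types for the ERK output genes, of the array type effect on cell division genes, of compressed values in the dominant-negative Rap1 sample and of dividing cells in S1 sample 3 were chosen after the result was seen. Among the 9 T4R samples, 77 values (levels of named genes, list means and 2 summary values, gene levels and list means with the table effect removed) were searched for a sample far from the others. In 14 of them 1 sample stood apart by a gap that chance gives in about 1 in 20 groups, and in 4.91% of 100000 random normal groups of 9. Of the 14, 10 belonged to dominant-negative Rap1, 3 to AIIB2 and 1 to LY294002, and the 77 values are not independent of each other.

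The dominant-negative Rap1 sample was highest in FN1 (8.61, next 7.21), TNFSF10 (11.99, next 10.42), THBS1 (9.33, next 8.44), IL1R1 (11.06, next 10.13) and RAP1A (11.31, next 10.71). Its means were highest for mesenchymal markers (8.90, next 8.53) and hypoxia genes (9.18, next 8.89). It was lowest in MKI67 (6.64, next 8.16) and in the means of cell division (7.39, next 8.69) and DNA replication genes (7.57, next 8.23). The AIIB2 sample was highest in IER3 (9.23, next 8.28), KRT10 (11.71, next 10.47) and the mean of keratinocyte differentiation genes (9.09, next 7.84), and LY294002 was lowest in GSTA4 (10.38, next 11.26). Of these 14, the gaps of 4 genes fell short of that size in the deposited values, where RAP1A read 10.91 (next 10.71), IL1R1 10.15 (next 9.77), MKI67 7.49 (next 8.16) and GSTA4 10.38 (next 10.82), so they rest on the removal of the table effect. The mean of the cholesterol synthesis genes differed between the 3 target classes (F = 15.2, adjusted p = 0.0144, limma).

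For the low cell division level with dominant-negative Rap1, compressed values on that array were argued against by an SD over genes of 1.39, within the 1.35 to 1.41 of the other 8 agents. Admixture of S1 cells was argued against by its position at 0.791 between S1 (0) and T4 (1), on 1153 genes that part S1 from T4 and the other 8 agents, which lay at 0.850 to 0.918. Array type, as an effect on these genes or through a sample measured on the other type, was argued against by its size. The table difference fitted without this sample had a cell division median of 0.20 (SD over members 0.31), against a gap of 1.28 to the next agent. The list mean was 7.41 as deposited in this sample, 8.69 to 8.93 in the first-table agents and 8.77 to 9.31 in the other second-table agents. On the genes that part the tables the sample lay at 0.386 (0 for the first, 1 for the second), with the other second-table agents at 0.574 to 1.11, which does not settle on which type it was measured. An effect of dominant-negative Rap1 on division is a biological candidate explanation that 1 sample cannot test.

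For the fall of ERK output genes in T4R, a difference between array types was argued against by the first table alone, where the list median was -1.05 (SD over its 3 agents 0.258). Fewer dividing cells as the whole cause were argued against, since the median was -1.26 with the cell division mean as a covariate. Cell division itself then stood at -0.09, which largely follows from its use as the covariate. The fit on that covariate leans in part on the dominant-negative Rap1 sample, with a mean of 7.41 against 8.69 to 9.31 in the other agents. Lower ERK signalling is the biological hypothesis that the agents' targets name. Phosphorylated ERK is not analysed here, so it stays a hypothesis.

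S1 sample 3 was at least 2-fold apart from S1 samples 1 and 2 in 577 genes, and in 517 after removal of the table difference seen in T4R. That difference correlated with the S1 one at 0.321 over genes, so an array type effect cannot be told apart from others, because no other S1 sample shares its table. T4 sample 3, which lies in the first table, deviated from its group in the same way (correlation 0.355 with the table effect removed and 0.391 as deposited), and that shared part does not follow array type. A batch shared by samples 3, or repeat measurement in samples 1 and 2 (16 genes 2-fold apart in S1 and 6 in T4), may lie behind it, and the labels name neither. More dividing cells in S1 sample 3 stay open too. The cell division median was 0.40 above S1 samples 1 and 2 together (SD over members 0.457), 0.06 above sample 1 and 0.91 above sample 2. The DNA replication mean, with the table effect removed, was 9.20 in S1 sample 3 against 7.95 and 7.96 in S1 samples 1 and 2. In T4 sample 3 it was 9.44, against 8.61 and 8.56 in T4 samples 1 and 2. No biological explanation was tested.

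The samples of each comparison were also regrouped. For T4R against T4, 1 of 100 splits, the real one, gave as many as 1358 genes and the highest other split 475. That split set GM6001, the MMP and ADAM inhibitor and LY294002 against the T4 samples and the second-table agents, and so partly repeats the real contrast within the first table. For T4R against S1, 1 of 100 splits gave as many as 2116 genes, and the highest other 35. For these 2 counts no other split drawn reached the real one. This cannot exclude chance, since the splits do not keep to the tables and so are not equivalent to the real one. Whether samples 1 and 2 of each line are independent is not known either. With 10 splits, the share cannot go below 0.1 for the other counts against S1 or T4. There the real split and the highest other gave 2452 and 6 genes for T4 against S1, 986 and 0 for the protease agents, 824 and 85 for the MAPK, PI3K and Rap1 agents and 561 and 2 for the EGFR and ITGB1 agents. For T4 against S1 the splits that part all 3 numbered pairs gave 6, 0 and 0 genes beside the real one. For the difference between the classes, the real count was 0, so 100 of 100 splits reached it by construction and say nothing about chance. The highest other gave 137. The splits with 137 and 120 genes kept the 3 first-table agents together, so that class and array type coincided. The table term then rested on S1 sample 3 against S1 samples 1 and 2. These counts therefore cannot be told apart from the difference of S1 sample 3. The splits with 90, 64 and 43 genes kept PD98059, the tyrphostin and mAb225 together, which points to a likeness of these 3 agent samples.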

How the results depend on the processing

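The estimated correlation, the fold threshold and each table alone were set before the data were examined, whereas fry, the replicate block without the table block and the fits without 3 samples together were chosen after seeing them. Of the refitted values of named genes, 2925 kept direction and side of the threshold, 29 gained and 55 lost a call and none turned. Of gene list values 4119 did so, 104 gained and 203 lost a call and 14 turned, and of counts and summary values 359 moved by less than 1.5 times or the agents' spread and 48 by more. The cause was not tested except where the setting itself gives it. Pseudocounts were not tried because the values were already on the log2 scale. With no detection calls, the signal over background that limits dim genes is unknown.

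A fold of at least 2 left 645, 304 and 297 genes for T4 against S1, T4R against T4 and T4R against S1, by its construction. Array weights gave 4180, 3160 and 3854 there, 3128 for the protease, 1677 for the MAPK, PI3K and Rap1 and 2210 for the EGFR and ITGB1 agents, and 18 between the classes. With no table block and quantile normalization across tables the EGFR and ITGB1 agents gave 1243. The second table alone, where S1 is a single sample, gave 1165 genes for T4R against S1 and turned DNA replication to -0.80 and ribosomal proteins to 0.24. With no filter, EGFR ligands and receptors turned to 0.0075 with the MAPK, PI3K and Rap1 agents.

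With the estimated correlation, 0, 0, 0, 1, 0 and 0 lists were called for the 3 main comparisons and the 3 classes, against 12, 14, 5, 14, 16 and 13. With fry, calls of cell division and ribosomal proteins were lost in T4 against S1 and in T4R against T4. In T4R against S1 fry called 2 lists, and 3 were called with the lower-mean genes up to the median left out and 3 after quantile normalization within tables. With a random table block the MAPK, PI3K and Rap1 agents had 10 lists.

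With the replicate number as a block, T4 against S1 gave 3661 genes and 17 lists, and NRF2 targets turned to -0.30. Without the table term beside the block it gave 1784 genes and 13 lists. Beside the calls given in the report, the block changed no other call of a named gene or list.

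Without S1 sample 3, T4 sample 3 and dominant-negative Rap1 together, the 3 classes gave 1800, 1559 and 862 genes and 2 between them, and the median slope of single agents was -0.427 (-0.503 with all samples). NRF2 targets in T4 against S1 turned to -0.30, DNA replication and mesenchymal markers in T4R against T4 to 0.14 and -0.15, DNA replication and ribosomal proteins with the protease agents to 0.20 and -0.0055, and interferon and heat shock genes with the MAPK, PI3K and Rap1 agents to -0.28 and 0.20.

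Leaving out each sample in turn gave 1687 to 2788 genes for T4 against S1, 948 to 1595 for T4R against T4 and 1584 to 2412 for T4R against S1. The protease agents ranged from 368 to 1205, the MAPK, PI3K and Rap1 agents from 392 to 956, the EGFR and ITGB1 agents from 194 to 759 and the difference between classes from 0 to 10. Lists called for T4R against S1 ranged from 3 to 5, with 3 without S1 sample 2, GM6001, PD98059 or LY294002. NRF2 targets in T4 against S1 ranged from -0.19 (without T4 sample 3) to 0.18 (without T4 sample 1). NF-kappaB genes with the MAPK, PI3K and Rap1 agents ranged from -0.41 to 0.0066 and interferon genes with the EGFR and ITGB1 agents from -0.34 to 0.30, the last of each without LY294002. The median slope of single agents ranged from -0.558 to -0.449.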

Other observations

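Some genes, chosen after their values were seen, took a level in T4R outside those of S1 and T4. MATN2, which encodes the matrix protein matrilin-2, stood at 7.38 ± 0.43 in S1, 7.60 ± 0.41 in T4 and 10.07 ± 0.46 in T4R (SD, n = 3, 3 and 9). It was 6.38-fold higher in T4R than in S1 (2.67 ± 0.30, limma adjusted p = 3.73e-05). SERPINE2, a serine protease inhibitor gene, lay at 9.01 ± 1.35, 9.40 ± 0.24 and 7.34 ± 0.08, lower in T4R than in S1 by -1.88 ± 0.32 on the log2 scale (adjusted p = 0.000891). The trypsinogen gene PRSS3 (-1.22 ± 0.24) and EMP3 (-2.18 ± 0.44) also passed as lower in T4R than in S1.

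BIK, which encodes a proapoptotic member of the BCL2 family, was higher than in S1 in both T4 (2.47 ± 0.24, adjusted p = 1.18e-05) and T4R (1.90 ± 0.20, adjusted p = 2.17e-05), as was the cell cycle phosphatase gene CDKN3 (2.17 ± 0.43 and 1.57 ± 0.35). The laminin-332 chain gene LAMB3 fell in T4R from 11.62 ± 0.11 to 10.07 ± 0.57 (-2.09 ± 0.29, adjusted p = 0.000461), and it did not pass against S1 (-0.72 ± 0.26, adjusted p = 0.0604). The basal keratin genes KRT5 and KRT14 were among the brightest, with 13.63 ± 0.07 and 13.93 ± 0.14 in S1, and passed in none of the 3 comparisons.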
